A study of Cereibacter sphaeroides 2.4.1 with 2 samples.

How the data were processed

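Total RNA of a lov deletion strain (Δlov) of Rhodobacter sphaeroides and of its wild type 2.4.1 was compared on 2 two-colour Agilent arrays. Per the labels' protocols, both strains grew under blue light of 20 µmol m-2 s-1 at an oxygen concentration of 90 µM, and RNA was isolated with hot phenol, treated with DNase and cleaned on spin columns. RNA was fragmented and labelled with a ULS kit, which attaches the dye chemically. On both arrays Δlov carried Cy3 and the wild type Cy5, so 0 arrays had swapped dyes and a dye effect could not be a term of any model. The labels assign biological samples 1 to 3 to array 1 and 4 to 6 to array 2 and do not say whether these were pooled. The p-values therefore measure the spread between 2 hybridisations, which may be partly technical. Both arrays carry the same scan identifier and scan date, so neither slide nor scan could be tested as a batch.

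Per the file headers, the spots were scanned and quantified with Feature Extraction 10.7.1.1, and the deposited intensity columns used here are the median pixel signals of each spot and of its local background in either channel. The deposited log10 ratio, per the file headers the processed Cy5 signal over the processed Cy3 signal, was used only to check the direction of the channels, and differed from that quotient by more than 0.001 in 463 of 30416 spots. The authors' value table holds a linear ratio with its scale, centring and direction not given in the sources used here. Each of its 15208 values per array equalled, within a relative tolerance of 1e-06, the background-subtracted Cy3 signal over the background-subtracted Cy5 signal of 1 spot, the same spot on both arrays, so it was read as Δlov over wild type without centring or dye normalization. The median of its column was 1.43 for array 1 and 1.76 for array 2, and it held 422 and 174 negative ratios, which have no logarithm. The submitters' processing notes name limma, with no version. The genome build and gene annotation of the array design were not given in the sources used here.

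Signals were read with limma 3.58.1 in R 4.3.3. The planned design called for mean spot signals. The files used here carry median signals, which were used in their place. Background was corrected by normexp with an offset of 50, and log ratios were normalized by loess within each array, with control spots at weight 0. Signs were turned so that a positive log2 ratio is higher in Δlov. Each array held 15208 spots besides 536 control spots, for 13218 probes. Spots of a probe were averaged, then probes of a feature, where a feature is all probes that share a systematic name. Of the features, 4316 had 3 probes, 70 had 2 and 130 had 1. A probe entered if it was well above background in at least 1 channel on both arrays, which held for 88.9% of the spots. Spots flagged as outliers (2 on array 1, 0 on array 2) were left out. This left 4431 of 4516 features, and the other 85 were not tested.

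The log2 ratios were tested against 0 with limma (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05). The number of arrays limits the precision. The median standard error was 0.05, which gives a 95% interval of 0.16 to either side on the log2 scale. A feature with one strain not well above background on both arrays is given as a lower bound ("at least N-fold"), computed from levels per channel after loess and Aquantile normalization and open to dye bias. The SD of the 77 negative-control spots was 231 intensity units in Cy3 and 273 in Cy5 on array 1, against 61.6 and 44.6 on array 2. Well above background were 88.3% of spots in Cy3 and 74.1% in Cy5 on array 1, and 98.2% and 94.3% on array 2. No spot was saturated.

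The test was checked on simulated data with 4431 features, of which 200 were changed. It recovered 50.3% of 1.5-fold, 93.2% of 2-fold and 98.6% of 4-fold changes. With no feature changed, it made 0.19 false calls on average. The simulated errors followed limma's own model and were independent between arrays. They held no dye or probe bias that repeats on both arrays, so the simulations do not cover false calls from such bias. In a further simulation 2215 features were changed, 200 of them 1.5-fold and the rest by random amounts. Of the 200, 95.1% were called, and 2.61% of all calls were unchanged features. A 2-fold rise of the Cy3 signal above the negative controls came out as 1.13 on the log2 scale, so such a rise is slightly overstated. Falls and rises of other sizes were not tried in this way.

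Of the array's features, 4372 bear only a number as their systematic name, and the files do not pair these numbers with gene names. None of the numbers (0 matches) occurs in the reference gene table of assembly ASM332471v1. The other 144 have a written name: an IGR label with a strand and often an interval, a locus tag marked as antisense or as a 3' or 5' end, or RSsh. IG-RSP0254/55 has none of these forms and no strand in its name, and was counted as intergenic sense. The 25 gene lists, the lov gene, its neighbours and 9 regulators that were to be reported could therefore not be assigned to features and are not reported. From the rule for named genes, the part that could be filled takes the 12 highest and 12 lowest features with adjusted p under 0.05 and the same sign on both arrays, and only 2 numbers per direction are printed. The following additions were made after the data were seen. Written names were grouped into classes and tested with limma's camera (preset correlation 0.01, Benjamini-Hochberg over 4 classes). The 10 highest and 5 lowest written names past the test were named, as was each region beside a gene whose symbol falls in 1 of the 25 lists. Tests of some technical explanations, listed in the closing paragraphs, were also added then.

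Intervals in the names were set against the gaps between annotated genes of ASM332471v1. Of 73, 54 matched a gap, with lengths within 3 bp and starts 2 to 109 bp apart. The flanking genes are named on that basis, intervals are printed as the array's names give them, and no position of the reference is printed. Alternatives tried were Agilent's processed signals, no background subtraction, a normexp offset of 0, median centring, other filters on dim probes, the median of probes, the authors' table, a trended robust prior, limma's treat against 1.2-fold, single probes, and each array alone. These alternatives were fixed before the data were examined.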

Results

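The arrays compared the transcriptomes of Δlov and wild-type Rhodobacter sphaeroides, a purple bacterium able to grow by respiration or photosynthesis, under blue light in semiaerobic culture. The lov gene encodes a short LOV domain protein, a flavin-binding blue-light receptor. The comparison asks which transcripts differ between the strains when this receptor is missing under the light it absorbs. Each of the 2 arrays hybridised both strains together, Δlov in Cy3 and wild type in Cy5, and gave 1 log2 ratio per feature. The median Cy3 signal was 5129 on array 1 and 5004 on array 2, and the median Cy5 signal was 3538 and 2716. Because the array's numbers for coding genes carry no names here, lov itself was not assigned to a feature, and the deletion and the dye direction were not checked against it. Directions below rest on the dye labels.

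The log2 ratio of Δlov over wild type differed from 0 for 2353 of 4431 tested features (53.1%). Of these, 1388 were higher and 965 lower in Δlov (limma, Benjamini-Hochberg adjusted p under 0.05). Strain and dye cannot be told apart here, because no array had swapped dyes. Most differences were small, since 1710 of these features differed by less than 1.5-fold. At least a 2-fold difference was measured for 209, of which 149 rose and 60 fell. By size alone, 343 features were at least 1.5-fold higher and 162 at least 1.5-fold lower on both arrays, and 503 of these 505 also passed the test. Against a minimum change of 1.2-fold (limma's treat), 433 features were higher and 237 lower. Among the 1342 features with a mean log2 brightness of at least 12, the balance turned, with 427 higher and 530 lower.

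The largest rise was that of feature 640072946, at 3.42 ± 0.01 (SD, n = 2 arrays) on the log2 scale, more than 10-fold (limma adjusted p = 0.00628). Feature 640070931 followed at 3.29 ± 0.03 (SD, n = 2) or 9.75-fold, measured by the 1 probe that passed the background filter. With all of its probes kept it was at 1.51. Feature 640072946 ranged from 2.75 without background subtraction to 4.24 with only probes above background in both channels. It kept rank 1 except under the latter filter, where it had rank 4 and another numbered feature reached 4.93, and in the authors' table, where it had rank 2 and another reached 4.21. The 12 highest features, 10 numbered and 2 with written names, ranged from 2.41 to 3.42. Among those that fell, feature 640071190 was not well above background in Δlov on both arrays and was at least 3.29-fold lower than in the wild type (measured log2 ratio -2.19, limma adjusted p = 0.00628). This bound rests on 1 probe. The log2 ratio of the feature was -1.28 with all probes kept, -0.77 without background subtraction and -3.36 with Agilent's processed signals. Feature 640069331 had a log2 ratio of -1.89 ± 0.19 (SD, n = 2), with Δlov above background on 1 of the 2 arrays. It was at -0.94, -0.65 and -3.10 under the same settings, in the same order. The 12 lowest features, all numbered, ranged from -2.19 to -1.53, 5 of them measured by 1 probe and 2 known only as a bound. The widest SD between arrays was 0.91 among these 12 and 0.39 among the 12 highest (n = 2).

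**Figure D1:**
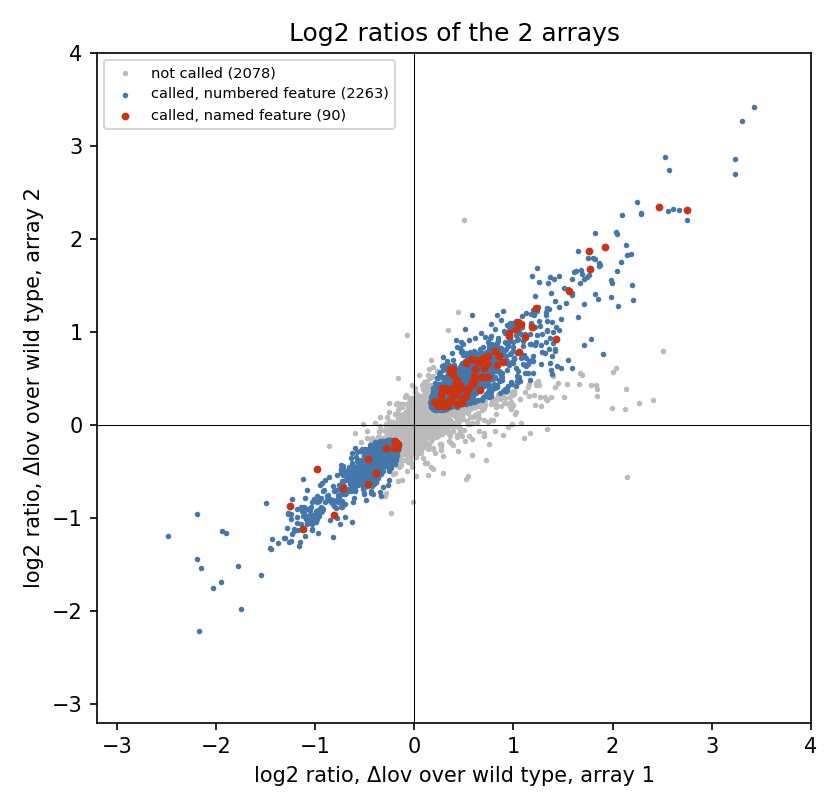
Log2 ratio of Δlov over wild type on array 1 (horizontal) against array 2 (vertical), 1 point per tested feature, with features past the limma test in blue (numbered) or red (written name) and the rest in grey. The 2353 features past the test lie either above 0 on both arrays (1388) or below 0 on both (965).

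The 2 arrays gave similar ratios. Across features, which are not independent replicates, Pearson's r was 0.899 and Spearman's rho 0.904, and 88.4% of features had the same sign on both. The difference between arrays had an SD of 0.23 on the log2 scale. No feature was at least 1.5-fold higher on one array and at least 1.5-fold lower on the other (0 of 4431).

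Features named as intergenic were among the largest rises. The intervals of IGR_0939_974899_974972_sense and IGR_1543_1632533_1632899_sense matched no gap between annotated genes of ASM332471v1. IGR_0182_antisense, IGR_0234_antisense and IGR_0293_antisense have no interval to match. The feature IGR_0939_974899_974972_sense, with an interval from 974899 to 974972 in its name, was 5.78-fold higher in Δlov (log2 2.53 ± 0.31, SD, n = 2). IGR_0182_antisense was 5.31-fold higher (2.41 ± 0.09). IGR_1943_2064697_2065079_antisense rose 3.78-fold (1.92), whereas the sense probe of the same interval, 2064697 to 2065079, fell with a log2 ratio of -0.27. The 2 strands of that interval differed by 2.19 ± 0.03 (SD, n = 2 arrays), by 1.15 ± 0.32 after median centring and by 0.89 ± 0.21 in the authors' table, and the sense feature passed the test in neither of these. IGR_2773_2919653_2919877_sense rose 3.30-fold (1.72 ± 0.06) and lies, by its interval from 2919653 to 2919877, between lptB, the ATPase of lipopolysaccharide transport, and hpf, which encodes a ribosome hibernation factor. The sizes of these rises depended on the normalization. Median centring and the authors' table leave in a fall of ratios with brightness. After median centring and in the authors' table, IGR_1943_2064697_2065079_antisense was at 1.02 and 0.74 and IGR_2773_2919653_2919877_sense at 1.03 and 0.76. IGR_0939_974899_974972_sense was at 2.07 and 1.92 there, and IGR_0182_antisense at 1.94 and 1.74. IGR_0234_antisense rose by 1.17 ± 0.35 on the log2 scale. IGR_1543_1632533_1632899_sense (2.83-fold) and IGR_0293_antisense (2.12-fold) were also higher after loess, but neither passed after median centring, at 0.25 (adjusted p = 0.0908) and -0.033 (0.845). In the authors' table both lay below 0, and IGR_0293_antisense passed as lower there (-0.30, adjusted p = 0.0477). After loess, all the features of this paragraph passed the limma test, with adjusted p from 0.00628 to 0.0240.

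Transcripts antisense to genes and gene ends also differed. The feature antisense to RSP_0247 rose 3.52-fold (antisense_RSP_0247, log2 1.82 ± 0.08, SD, n = 2), and asRSP3018_No1 rose 2.17-fold (1.12 ± 0.09). The feature 3'RSP3584 was at 1.24 after loess, at 0.20 after median centring and at -0.087 in the authors' table, and did not pass in the latter 2. The 5 lowest written names past the test were IGR_1603_1700623_1704124_sense (-1.12), IGR_0552_sense (-1.07, and -2.42 after median centring), 3'RSP6250 (-0.89), IGR_0148_sense (-0.73) and IGR_0272_sense (-0.70). The interval of IGR_1603_1700623_1704124_sense matched no gap between annotated genes of ASM332471v1. The spread between arrays was widest for IGR_0148_sense, with an SD of 0.36 (n = 2), from -0.98 on array 1 to -0.47 on array 2, and its call was lost in the authors' table (-0.37, adjusted p = 0.0581).

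**Figure D2:**
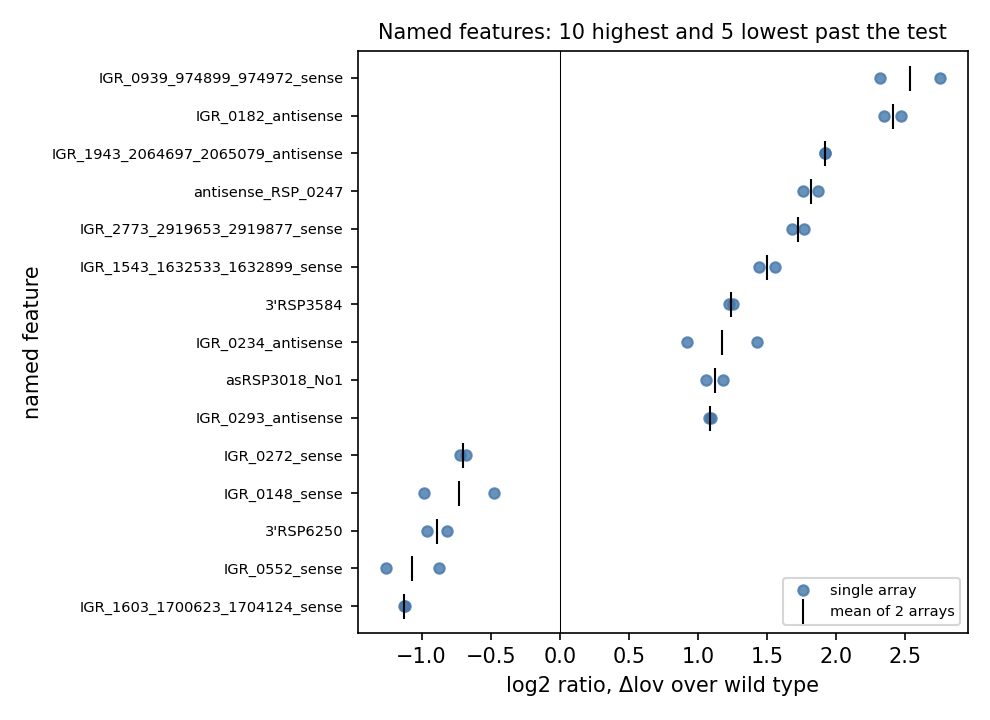
Log2 ratio of Δlov over wild type (horizontal) for the 10 highest and 5 lowest features with a written name among those past the limma test, 1 dot per array and a bar for the mean of the 2 arrays. The means run from -1.12 to 2.53, and both arrays lie on the same side of 0 for each feature.

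As classes, features with written names lay above the numbered ones after loess and with Agilent's processed signals. The direction against all numbered features depended on the normalization. The classes were brighter, with median log2 brightness from 12.5 (gene ends) to 14.7 (intergenic sense), against 11.4 for numbered features. Against numbered features of similar brightness, all written names together lay higher by 0.41 ± 0.08 after loess and 0.40 ± 0.01 after median centring (SD, n = 2 arrays). No class passed with an estimated correlation (camera adjusted p = 0.442 for each). With 2 arrays that form of camera has little power and cannot decide. Under it the camera p of intergenic sense features rose from 0.0640 to 0.297, although their estimated correlation of 0.0064 lay below the preset 0.01. The estimate lay far above the preset for intergenic antisense features (0.19), features antisense to a gene (0.26) and gene ends (0.13). For these classes the preset p-values therefore assume less correlation than was estimated. The following camera p-values use the preset correlation. Features of the same region count separately in the classes, and camera takes them as separate members. IGR_0680a, IGR_0680b and IGR_0680c share the same interval and strand and all rose (1.03, 0.54 and 0.81). Likewise asRSP3018_No1 and asRSP3018_No2 both count as antisense to a gene. Of 48 intergenic antisense features 26 rose and 4 fell, with a median log2 ratio of 0.29 (camera adjusted p = 0.00355). Of 22 features antisense to a gene 12 rose and 1 fell (median 0.27, 0.46 on array 1 and 0.22 on array 2, adjusted p = 0.0105), and of 11 gene ends 8 rose and 1 fell (median 0.47, adjusted p = 0.0169). Of 59 intergenic sense features 28 rose and 8 fell, with a median of 0.23, a shift that did not pass (adjusted p = 0.0640). Among 4289 numbered features 1312 rose and 951 fell (median 0.06). Relative to the numbered features, the shift turned negative after median centring for 3 classes, to -0.31 for intergenic antisense, -0.54 for intergenic sense and -0.056 for antisense to a gene. For gene ends it was 0.015 there, and in the authors' table it was negative for all 4 classes. Camera passed as lower for intergenic antisense and intergenic sense features, after median centring (adjusted p = 0.00196 and 1.13e-06) and in the authors' table (6.35e-05 and 2.64e-07), though with an estimated correlation again no class passed (0.961 and 0.960 for each).

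**Figure D3:**
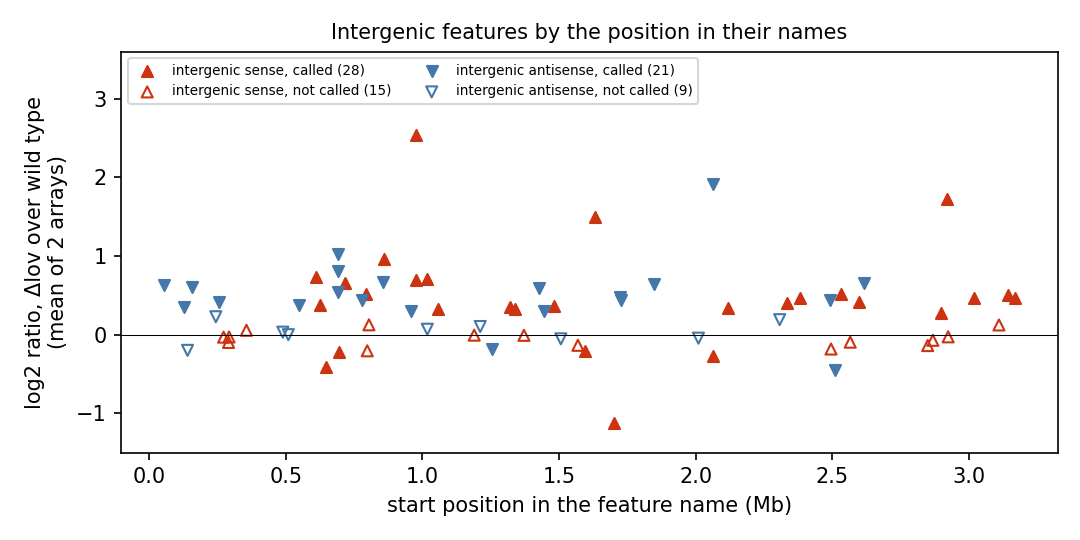
Mean log2 ratio of Δlov over wild type (vertical) of the 73 intergenic features with an interval in their name, by its start position in Mb (horizontal), with sense features as red upward and antisense features as blue downward triangles, filled where past the limma test. The highest is IGR_0939_974899_974972_sense at 2.53 and the lowest IGR_1603_1700623_1704124_sense at -1.12.

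Regions beside genes of photosynthesis, the RpoE response, heme and the ribosome were measured for 8 features, of which, after loess, 1 was higher, 1 was lower and 6 did not pass the test. After median centring, and also in the authors' table, 0 were higher, 6 were lower and 2 did not pass. Both settings leave in a fall of ratios with brightness. After median centring the median of all features was -0.47 at a mean log2 brightness of 13 to 15 and -1.05 at 15 and over. A pass as lower under these settings need not be a fall in Δlov. These probes measure the region and not the neighbouring gene. Beside appA, which encodes a blue-light and redox sensor of photosynthesis gene control, IGR_0140_156483_156950_antisense was 1.52-fold higher after loess (log2 0.61 ± 0.005, SD, n = 2, limma adjusted p = 0.00903), but at -0.26 after median centring (adjusted p = 0.0820) and at -0.53 in the authors' table, where it passed as lower (adjusted p = 0.00858). Between ppaA, a regulator of photopigment genes, and bchF of bacteriochlorophyll synthesis, IGR_1889_2010158_2010529_antisense was at -0.05 ± 0.25 (limma adjusted p = 0.748). Beside rpoE, which encodes the sigma factor of the singlet oxygen response, IGR_2710_2849390_2849603_sense was at -0.14 ± 0.05 (adjusted p = 0.0970), and passed as lower without background subtraction (-0.11), at a brightness of at least 12 (-0.14), after median centring (-0.47) and in the authors' table (-0.65). Beside hemP, IGR_0124_140184_140533_antisense was at -0.20 ± 0.48, with opposite signs on the 2 arrays (0.14 and -0.54). It passed as lower only after median centring (-0.31), in a fit with a spread shared by all features, and not in the authors' table (-0.45, adjusted p = 0.120). At ribosomal protein genes, IGR_1204_1255038_1255214_antisense beside rpmF fell by 0.18 on the log2 scale (limma adjusted p = 0.0498), a call lost with a normexp offset of 0 (0.0534), with all probes kept (0.0591) and with the median of probes (0.0659). The regions beside rpsT, rpsO and between rplA and rplJ did not pass after loess, at 0.12, -0.07 and -0.03. The region beside rpsT passed in both directions, as higher with Agilent's signals (0.21), without background subtraction (0.14) and at a brightness of at least 12 (0.12). After median centring all 3 passed as lower, at -0.55, -0.89 and -0.59, and in the authors' table they did so at -0.81, -1.16 and -0.83.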

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

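Outside the measured features, 4 of the 57 control probes examined, corner marks left out, lay more than 3 SD above the mean of the negative controls in both channels on both arrays. The probes were ETG05_66023, ETG10_195139, DCP_22_0 and DCP_1_0. ETG05_66023 read 3356 in Cy3 on array 1 against a negative-control mean of 2280. On array 2 it read 2899 against 1976. No explanation was tested, and the probes entered no comparison.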

How the results depend on the processing

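No paired analysis was possible because the series has 1 group, in which each array already holds both strains. The lov gene and the planned gene lists have no alternative values, since no feature was assigned to them. The classes, the regions beside list genes and their alternatives were chosen after the data were seen. Where no cause is named, the cause was not tested. The count of 2353 features past the test stayed within 1.5 times under 9 settings, from 2131 to 3321. Single features changed direction mostly after median centring and in the authors' table. With median centring, 1792 of the 2353 kept their sign and passed, and 116 changed sign, 30 of them past the test. There the fit gave an unlimited prior, so all features share 1 spread and its p-values are not comparable in size. With the authors' table, 1864 kept their sign and passed, and 236 changed sign, 82 of them past the test. Before loess, ratios fell with brightness, from a median of 0.49 in 1448 features under a mean log2 brightness of 11 to -1.05 in 146 features of 15 and over. After loess a smaller fall remained, from 0.21 to -0.14 in the same 2 groups. Array 1, with the wider background, limits the dim features.

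For features past the test, a brightness of at least 12, which leaves 1342 features, gave 957 (427 higher, 530 lower). Limma's treat gave 670 (433 and 237), and single probes gave 5403 (2930 and 2473) of 12010. The authors' table gave 1541 lower. For features at least 1.5-fold different on both arrays (505, 343 higher and 162 lower), no background subtraction gave 219 (163 and 56), median centring 940 (611 and 329), brightness of at least 12 gave 149 (104 and 45) and the authors' table gave 1618 (967 and 651). On 1 array alone the counts lay between 632 and 798, with 424 to 594 higher and 204 to 208 lower. The 798, and 594 higher, were reached without replicate 2, on the noisier array alone.

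Pearson's r between arrays (0.899) was 0.926 with Agilent's processed signals, 0.943 without background subtraction, 0.890 with offset 0 and 0.919 with median centring. It was 0.950 for probes above background in both channels, 0.969 at a brightness of at least 12, 0.880 with the median of probes and 0.936 in the authors' table. The share with the same sign (88.4%) was 90.9% with Agilent's signals, 91.9% at a brightness of at least 12, 86.1% with the median of probes and 92.9% in the authors' table.

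Class medians are given relative to numbered features, and camera with an estimated correlation has little power with 2 arrays. The estimate was 0.19 for intergenic antisense features, 0.26 for features antisense to a gene and 0.13 for gene ends, against the preset 0.01. Those of intergenic antisense features (0.23), features antisense to a gene (0.21) and gene ends (0.41) no longer passed with an estimated correlation in camera (adjusted p = 0.442 each). Fry, which tests each class against no change and not against other features, did not pass for them either (adjusted p = 0.0848, 0.121 and 0.0848). Intergenic sense features (0.17) did not pass with an estimated correlation either (0.442), and with the preset one they passed as higher with Agilent's signals (0.22), without background subtraction (0.17), with probes above background in both channels (0.19), at a brightness of at least 12 (0.35) and with the median of probes (0.16). With median centring the 4 classes lay at -0.31 (intergenic antisense), -0.54 (intergenic sense), -0.056 (antisense to a gene) and 0.015 (gene ends). In the authors' table they lay at -0.49, -0.70, -0.14 and -0.15 in the same order. Under both settings the 2 intergenic classes passed camera as lower (adjusted p = 0.00196 and 1.13e-06, then 6.35e-05 and 2.64e-07), and no class passed with an estimated correlation (0.961 and 0.960). On 1 array alone, intergenic antisense features lay between 0.22 and 0.26, intergenic sense features between 0.12 and 0.16 and features antisense to a gene between 0.18 and 0.40, the highest on array 1.

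Among single features, 12 of the values under other settings turned sign. With Agilent's signals IGR_0284_292185_292422_sense was at 0.053 and IGR_2728_2868236_2868475_sense at 0.0057. With median centring and in the authors' table, IGR_0293_antisense was at -0.033 and -0.30, IGR_0140_156483_156950_antisense at -0.26 and -0.53, IGR_2955_3110237_3110774_sense at -0.55 and -0.81, and IGR_1889_2010158_2010529_antisense at 0.20 and 0.24. In the authors' table IGR_1543_1632533_1632899_sense was at -0.033 and 3'RSP3584 at -0.087. On 1 array alone, IGR_0284_292185_292422_sense lay between -0.064 and 0.0032, IGR_1889_2010158_2010529_antisense between -0.22 and 0.13, and IGR_0124_140184_140533_antisense between -0.54 and 0.14. IGR_0148_sense no longer passed in the authors' table (-0.37). Counting it, 10 values kept their sign and no longer passed, and 12 newly passed.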

Other observations

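The tests of brightness, of probe number, of loess, of the share of a single probe and of array closeness as the whole cause were chosen only after the results were seen. Numbered features that differed strongly also lay next to each other in number. Runs of at least 4 consecutive numbers, each at least 1.5-fold different on both arrays, occurred 7 times among those lower in Δlov, with 42 features, and 4 times among those higher, with 18. Shuffled numbers gave 0.0064 and 0.103 such runs on average, and at most 1 and 3. The longest lower run held 7 features with a median log2 ratio of -0.80, and the longest higher run 6 with a median of 0.99. The longest run in any shuffle held 5 lower or 7 higher features, so the length of the longest higher run lies within what shuffling gave. In blocks of 100 numbers, medians ran from -0.43 to 0.38, while 10000 shuffles stayed between -0.14 and 0.31. The gene content of these runs was not analysed here.

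The large share of features past the test (53.1%) may have more than 1 source. Loess left in a fall of ratios with brightness. The median was 0.21 in 1448 features under a mean log2 brightness of 11 and -0.14 in 146 of 15 and over. Whether this fall adds to the calls was not tested. Uneven hybridisation across the surface is argued against, since duplicate spots of a probe at least 50 rows apart still correlated at 0.707 or more on either array. A part may belong to single probes, since 57.7% (95% interval 54.3 to 61.1) of the variance that repeated between arrays was not shared by other probes of the feature. The intraclass correlation of probes within features was 0.408 (0.377 to 0.438), between the values set beforehand for and against bias of single probes as the whole cause. Dye bias of whole transcripts cannot be told apart from the lov deletion, because 0 arrays had swapped dyes.

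The written names lay above all numbered features after loess, and each class did so with Agilent's processed signals. After median centring the difference was -0.31 (-0.15 on array 1 and -0.45 on array 2), the outcome set for loess as its source. That outcome cannot tell loess from the fall of ratios with brightness that median centring leaves in. There numbered features of similar brightness lay at -0.62 and the written names at -0.22. Their median of 0.28 after loess exceeded that of 100% of 10000 lists matched on brightness (centred on -0.12), by 0.41 ± 0.08 (SD, n = 2 arrays), and after median centring it exceeded 100%, by 0.40 ± 0.01, against brightness alone and against loess as the source of this matched difference. The 32 names with 3 probes exceeded 99.9% of matched lists with 3 probes, by 0.26 ± 0.09, and 100% after median centring, against few probes as the whole cause, but names with 1 probe lay higher (0.42 against 0.12), so a partial role stays open. Such lists take features as independent. With an estimated correlation, here 0.099, the shift of all written names after loess did not pass (camera p = 0.357), but that test has little power with 2 arrays. Dye bias that differs between kinds of transcript and an effect of the lov deletion both stay open and were not tested here.

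Consecutive numbers had similar log2 ratios, with a correlation across features of 0.367 over 4174 pairs, against at most 0.0565 in 10000 shuffles. Closeness on the array as the whole cause is argued against, since probes of consecutive features at least 50 rows apart kept 86.6% (80.1 to 93.2) of the correlation of nearer ones. The far correlation of 0.227 (0.209 to 0.244) lies between the bounds set beforehand, which leaves a partial role of closeness open. The correlation at distance 1 was 2.09 times that at distance 10 (0.176). This lies above the ratio set beforehand for the hypothesis that neighbouring numbers mark genes transcribed together. The correlation was still 0.131 at distance 20, above the highest shuffled value. The ratio therefore cannot show that genes transcribed together account for the whole correlation, and gene positions were not checked.

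Probes of a feature did not always move together. Of 2176 features past the test with at least 2 probes, 1732 (79.6%) had all probes on the side of their mean. Among the 4141 tested features with at least 2 probes, 32 had probes at least 1.5-fold from 0 in opposite directions.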
